A study of Mus musculus with 5 samples.

How the data were processed

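RNA from anti-FLAG precipitates of NSC-34 cells was measured on 5 single-colour Affymetrix arrays (biotin label), 3 from cells with the 3XFLAG-SMN construct and 2 from cells without it. Per the labels' protocols, bound protein was released with FLAG peptide and digested with proteinase K, RNA was recovered by phenol-chloroform extraction, and 300 to 500 ng of precipitated RNA entered labelling. The deposited values are on the log2 scale, and RMA (background correction, quantile normalization and probe summary) is named in the submitters' processing notes; its version and settings are not given in the sources used here. The log2 scale was read from the range of the deposited values, 1.28 to 14.15, with 0 missing. Because RMA forces the arrays toward a common distribution, a general difference in the amount of RNA recovered between the precipitates is not visible in the values.

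Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The table held 34760 probe sets. The files do not mark control probe sets; the 6573 whose IDs lie below the lowest ID named in the platform annotation were taken as presumed controls and left out, which kept 28187; this ID rule was chosen after the files were opened. Of these, 21640 carried 1 gene symbol, 1321 several and 5226 none in the platform annotation, and only probe sets with 1 symbol were named. By gene ID, 21553 of them matched a mouse RefSeq gene table (assembly GRCm38), which changed 0 symbols. That table was also used for biotypes and for finding the genes within which snoRNAs lie; no coordinates are printed because the array files name no build.

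The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no block), with Benjamini-Hochberg adjustment over all 28187 probe sets and a threshold of 0.05. The fit had 3 residual and 3.8 prior degrees of freedom. Values per group are means of log2 values with SD, folds are 2 to the power of the log2 difference, and confidence intervals are 95% intervals from the moderated fit. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, on the brightest probe set of each of 19938 genes, adjusted over the 27 of 28 lists with at least 5 measured genes. The same lists were tested with a correlation estimated per list and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The tests, gene lists, naming rule and all alternatives, except those stated otherwise in the closing part, were fixed before the data were examined.

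The naming rule took the 12 genes with the largest positive and the 8 with the largest negative difference among probe sets past the threshold whose groups did not overlap, with 1 gene symbol and a mean signal above the median probe set. Where fewer passed, the list was filled by the smallest unadjusted p under the same conditions. The rule added the 2 members of smallest unadjusted p for lists described in detail, and Smn1, Anxa2, Nrn1, Gap43, Actb, Elavl4, Cox4i2 and Gapdh whatever their values.

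The fit was tested on simulated data with the real probe sets' means and spread. Over 20 draws with 200 of 28187 probe sets changed, the adjusted test recovered 0% of changes of 1 log2 unit, 63.6% of changes of 2 and 86.8% of changes of 3. The list test recovered a shift of 0.5 on the 61 ribosomal protein genes in 100% of draws. Simulated values were drawn independently for each gene, whereas the correlation estimated for that list in the data was 0.057. The draws therefore do not show how the list test behaves on correlated genes. Alternatives were cyclic loess scaling, centring on the brighter probe sets, brighter probe sets only, trend and robust variance moderation, array weights, the replicate number as a block, leaving out each array, the mean of all probe sets of a gene, a 1.5-fold minimum, the all-probe-set table, and the list tests named above. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.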

Results

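RNA that co-precipitated with the survival of motor neuron protein (SMN) was profiled on microarrays. SMN is the protein lost in spinal muscular atrophy and is known for loading Sm proteins onto spliceosomal small nuclear RNAs. The cells were NSC-34, a mouse motor neuron-like hybrid of neuroblastoma and spinal cord motor neurons, either carrying a 3XFLAG-tagged full-length SMN construct or carrying no tagged construct. The labels give the differentiation in 1% serum as 3 days in one protocol and as 48 hours before doxycycline in another. Both kinds of cell then received 3 µg/ml doxycycline for 3 days and were irradiated with ultraviolet light at 400 mJ/cm2 and subjected to anti-FLAG precipitation. The arrays comprised 3 FLAG-SMN precipitates (FLAG-SMN IP) and 2 precipitates from cells without the construct (control IP), the latter measuring RNA that the beads retain without a tagged protein. The small number of arrays limits the precision of every value. RNA of the lysates before precipitation was not analysed here, so a difference between the precipitates was not corrected for the RNA level in the cells.

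The 5 arrays had closely matched medians, from 5.25 to 5.39 on the log2 scale over 28187 probe sets. RMA forces the arrays toward a common distribution, so this match says nothing about the precipitates. FLAG-SMN IP replicates 2 and 3 were the closest pair, with Pearson r = 0.989 across probe sets, and the control IP arrays reached r = 0.98. FLAG-SMN IP replicate 1 stood apart from its own group, with r = 0.964 and 0.968 to replicates 2 and 3. Correlations between arrays of different groups spanned 0.954 to 0.977, overlapping those within the FLAG-SMN group. Probe sets are not independent replicates, so these r values describe the arrays and carry no test. No arrays were duplicates of each other, the closest pair differing by up to 3.57 log2 units at a single probe set.

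**Figure D1:**
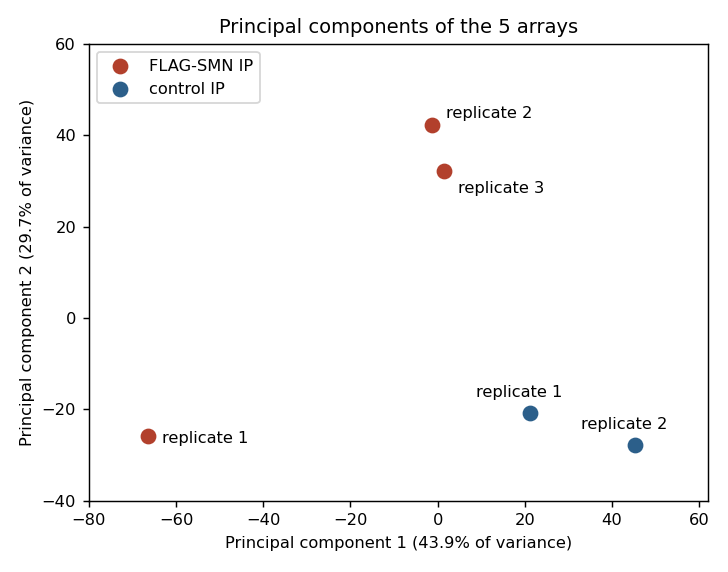
Principal components 1 and 2 (unitless scores, with the percentage of variance on each axis) of the log2 values of 28187 probe sets, 1 point per array, red for FLAG-SMN IP and blue for control IP. Component 1 (43.9% of variance) sets FLAG-SMN IP replicate 1 at -66.5 apart from the rest, and component 2 (29.7%) separates FLAG-SMN IP replicates 2 and 3 (42.3 and 32.1) from the control IP arrays (-20.8 and -27.8) and FLAG-SMN IP replicate 1 (-25.8).

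The comparison of FLAG-SMN IP with control IP asks which RNAs are present in SMN-containing particles. Smn1 itself had log2 values of 9.89, 9.50 and 9.46 in the FLAG-SMN IP arrays and 8.10 and 7.64 in the control IP arrays. The labels do not say whether the construct is of mouse or human sequence, so it is not known whether this probe set reads RNA of the construct, of the cells' own gene or of both. Its mean was 9.62 ± 0.24 (SD, n = 3) against 7.87 ± 0.33 (SD, n = 2), a log2 difference of 1.74 (SE 0.23; 3.35-fold; limma adjusted p = 0.0877), with all 3 FLAG-SMN arrays above both control arrays. That value did not pass the adjusted threshold of 0.05. Without FLAG-SMN IP replicate 1 the difference was 1.61 and passed (limma adjusted p = 0.0259). With FLAG-SMN IP replicate 2 or 3 left out instead, 0 probe sets passed.

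Among annotated genes, 3 non-coding RNAs were higher in FLAG-SMN IP past the adjusted threshold. Scarna17, a guide RNA of the Cajal body class, was 6.82-fold higher (95% confidence interval 4.74 to 9.82; log2 difference 2.77, SE 0.22; limma adjusted p = 0.0448) and reached 12.39 ± 0.17 (SD, n = 3) against 9.62 ± 0.34 (SD, n = 2). Gas5 is a long non-coding RNA whose introns carry box C/D small nucleolar RNAs (snoRNAs). It was 5.63-fold higher at 1 of its 4 probe sets (log2 difference 2.49, SE 0.21, limma adjusted p = 0.0448). The differences of all 4 were positive, from 1.03 to 2.49, but the others did not pass (limma adjusted p from 0.0853 to 0.269). The brightest of them, used for Gas5 in the list tests, gave 1.55 (limma adjusted p = 0.269). Gm24463, annotated as a long non-coding RNA, was higher by a log2 difference of 3.17 (SE 0.29; adjusted p = 0.0496), with positive differences at all 3 of its probe sets. Its control values, 3.58 and 4.48, lay below the medians of the presumed control probe sets in those arrays (4.49 and 4.54). The size of its difference is therefore uncertain, and no fold is given. The only other probe set past the threshold in this direction, 10461150, has no gene name in the annotation used and a log2 difference of 2.38 (adjusted p = 0.0448); it falls outside the rule for named genes and was singled out after its value was seen.

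Lower in FLAG-SMN IP were 5 protein-coding genes. Crabp1, which encodes a cytoplasmic retinoic acid binding protein, was 9.09-fold lower (log2 difference -3.18, SE 0.20; limma adjusted p = 0.0243), at 7.20 ± 0.088 (SD, n = 3) against 10.38 ± 0.26 (SD, n = 2). The secreted signalling protein gene Wnt1 was 5.64-fold lower (-2.50, adjusted p = 0.0448), the neuropeptide gene Rln3 4.69-fold lower (-2.23, adjusted p = 0.0496), and Pcolce, an enhancer of procollagen processing, 4.36-fold lower (-2.13, adjusted p = 0.0496). Wnt1 was at 4.65, 4.69 and 4.68 in FLAG-SMN IP, little above the medians of the presumed control probe sets there, so its fold is uncertain. Cacng3, an accessory subunit of calcium channels and AMPA receptors, was also lower (-2.66, limma adjusted p = 0.0243). It was at 4.03, 4.04 and 4.22 in FLAG-SMN IP, below the medians of the presumed control probe sets there (4.45, 4.33 and 4.30). The size of its difference is therefore uncertain, and no fold is given. Its mean signal lay below the brightness minimum for named genes, and it was added after its value was seen. In each of these genes every FLAG-SMN array lay below both control arrays, which the naming rule required for all but Cacng3.

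In all, 9 of 28187 probe sets passed the adjusted threshold in limma, 4 higher and 5 lower. At an unadjusted p under 0.05 there were 1166 higher and 1779 lower, 2945 in total where 1409 are expected by chance. The groups did not overlap at 7120 probe sets (25.3%), a share that chance puts at 20%. Calls depended on single arrays: leaving out FLAG-SMN IP replicate 1 gave 159 higher and 191 lower, including all 9, whereas leaving out FLAG-SMN IP replicate 2 or 3, or control IP replicate 1 or 2, left 0 in limma. Testing all 34760 probe sets of the table, without the ID rule chosen after the files were opened, left 0, with 389 higher and 732 lower at least 2-fold apart with an unadjusted p under 0.05. The replicate number as a block left 0, with 443 and 619 on that criterion. Cyclic loess scaling of the deposited values also left 0, while 326 higher and 409 lower probe sets were at least 2-fold apart with an unadjusted p under 0.05.

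The next genes by unadjusted p did not pass the threshold, and their values are given without a call. On the higher side these included 4 box C/D snoRNAs, a class that guides ribosomal RNA methylation: Snord15a (log2 difference 2.23, adjusted p = 0.0536), Snord42a (2.01, adjusted p = 0.0729), Snord47 (1.77, adjusted p = 0.0864) and Snord14e (1.77, adjusted p = 0.0998). Snord47 lies within Gas5. Also on this side were Zc3h3 (2.41, adjusted p = 0.0853), Csrp2 (1.40, adjusted p = 0.0853) and Selenoh (1.54, adjusted p = 0.0957). The other probe set of Zc3h3 had a difference of 0.018 (adjusted p = 0.999). On the lower side stood the nicotinic acetylcholine receptor subunit genes Chrna3 (-3.95, SE 0.40) and Chrnb2 (-1.99, SE 0.20), the thrombin receptor family gene F2rl2 (-1.83, SE 0.18) and the axonal adhesion gene Nfasc (-1.99, SE 0.20), each with adjusted p = 0.0536. In FLAG-SMN IP replicate 1 Chrna3 was at 4.42, below the presumed control median of 4.45. All of these named genes kept the groups apart on every array, but the naming rule required this, so it adds no support. Without FLAG-SMN IP replicate 1 each of them passed, with limma adjusted p from 0.00515 for Chrna3 to 0.0313 for Snord14e. Leaving out FLAG-SMN IP replicate 2 or 3 instead left 0 probe sets past the threshold.

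**Figure D2:**
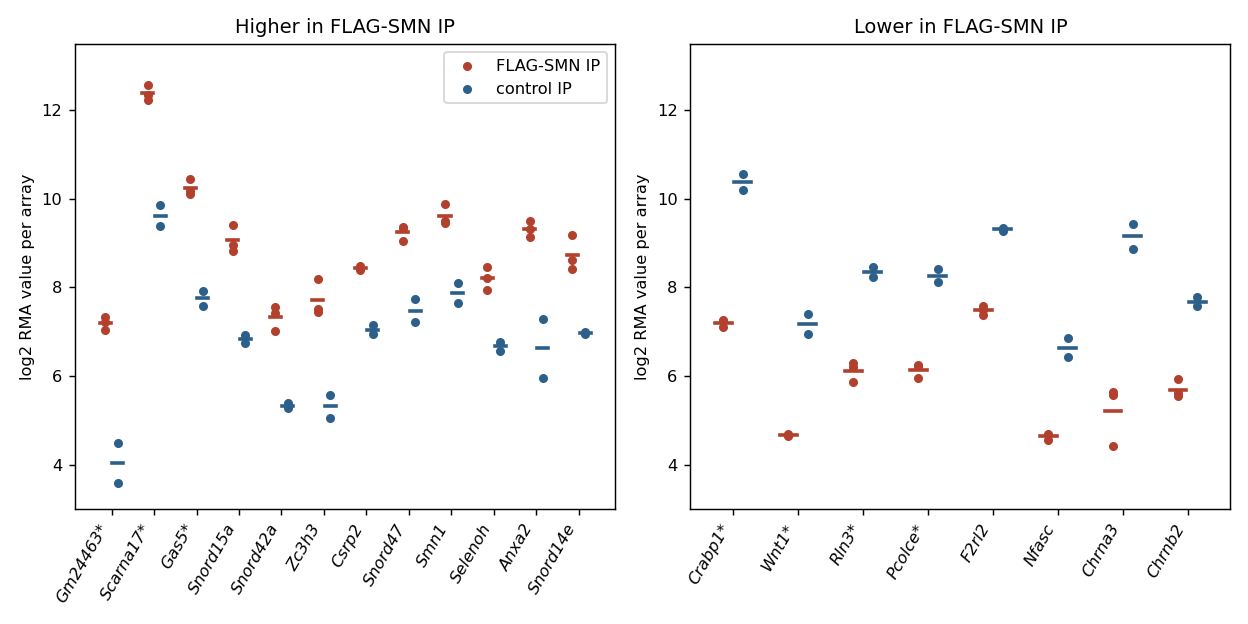
Log2 RMA values (y axis, 1 point per array, bar at the group mean) of the genes the naming rule selected (x axis) on the higher side (left) and lower side (right), red for 3 FLAG-SMN IP arrays and blue for 2 control IP arrays, with an asterisk at limma adjusted p under 0.05. The naming rule admitted only genes whose groups did not overlap. Scarna17 sits at 12.39 against 9.62 on average and Crabp1 at 7.20 against 10.38.

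Other genes fixed for reporting gave mixed values. Anxa2, which encodes a calcium-dependent membrane-binding protein, had a log2 difference of 2.69 (SE 0.38; 6.46-fold; limma adjusted p = 0.0957), at 9.32 ± 0.18 (SD, n = 3) against 6.62 ± 0.94 (SD, n = 2); it passed without FLAG-SMN IP replicate 1 (2.60, adjusted p = 0.0332), and the control arrays were at 5.96 and 7.29. Cox4i2, an isoform of a cytochrome oxidase subunit, gave 1.40 (adjusted p = 0.151; 1.52 and adjusted p = 0.0481 without that array), Nrn1 (neuritin) 0.26 (adjusted p = 0.953), and Actb -0.61 (adjusted p = 0.333). Elavl4, which encodes the neuronal RNA-binding protein HuD, gave -0.73 (adjusted p = 0.425). Gap43, a growth cone gene, gave -0.30 (adjusted p = 0.983), with 10.7 in FLAG-SMN IP replicate 1 and 7.38 and 7.47 in replicates 2 and 3. Without replicate 1 the difference of Nrn1 was -0.22 and that of Gap43 -1.39. With FLAG-SMN IP replicate 2 or 3 left out instead, 0 probe sets passed, so Anxa2 and Cox4i2 did not. Gapdh had no probe set of its own, as 11 probe sets carry its name together with other genes.

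A descriptive count took probe sets at least 2-fold apart with an unadjusted p under 0.05, and found 325 higher and 460 lower. Of the higher ones, 151 carry 1 gene name and 139 carry none; of the lower ones, 404 carry 1 gene name and 41 none. Over all tested probe sets, 21640 carry 1 gene name and 5226 none. Leaving out control IP replicate 1 moved the lower count to 728. These counts are not corrected for multiple testing.

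The fixed list of non-coding RNAs and snoRNA host genes was higher as a group. The list held 75 genes, with a median log2 difference of 0.60; 22 were higher and 0 lower at an unadjusted p under 0.05, 17 higher when adjusted over the list alone and 1 (Scarna17) over all probe sets. The camera test against the other genes gave adjusted p = 1.41e-11 with the preset correlation and adjusted p = 0.851 with an estimated correlation. Scarna17 and Snord15a had the smallest p-values. Members that passed over the list alone also included the box C/D snoRNA Snord33 (1.58) and the host transcript Snhg5 (2.08). FLAG-SMN IP replicate 1 lay 0.82 below the mean of replicates 2 and 3 on this list (difference -0.82), and without it the median was 0.95. The median was 0.28 without replicate 2 and 0.27 without replicate 3, and the list passed in each case. By annotated biotype over all genes, the median was 0.62 for 53 snoRNAs, but 0.00075 for 675 long non-coding RNAs and 0.0225 for 297 microRNAs. The 7 small nuclear RNAs had a median of 0.040, with 0 higher and 0 lower at an unadjusted p under 0.05. By these medians the shift did not extend to long non-coding RNAs, microRNAs or small nuclear RNAs. Whether those classes lay above the presumed controls was not examined. Some classes of 1 to 3 genes had positive medians: guide RNAs 1.88, RNase P RNA 0.85, RNase MRP RNA 0.88, Y RNAs 0.65 and ribosomal RNA 2.37. Telomerase RNA (-1.50) and 33 genes of the miscellaneous RNA class (-0.091) had negative ones. Unspliced host RNA that contains a snoRNA was not measured separately.

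Cytosolic ribosomal protein genes were higher as a group by a smaller amount. Their median log2 difference was 0.28 over 61 genes; 13 were higher and 0 lower at an unadjusted p under 0.05, with 0 passing when adjusted over the list alone or over all probe sets. The camera adjusted p was 7.09e-07, and adjusted p = 0.851 with an estimated correlation. Rpl7 gave 1.09 (SE 0.22; adjusted p = 0.171), with positive differences at all 4 of its probe sets. Rpl7a gave 1.64 (SE 0.38; adjusted p = 0.215) at the probe set used, while its 3 probe sets did not share a sign. Processed pseudogenes of this family are near-identical in sequence, so single members are uncertain. Leaving out control IP replicate 2 reduced the list median to 0.14.

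Glycolysis genes were the third list higher as a group, with a median of 0.52 over 14 genes. Of these, 3 were higher and 0 lower at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone or over all probe sets; camera gave adjusted p = 0.000189, and adjusted p = 0.851 with an estimated correlation. Pfkp, a phosphofructokinase gene, gave 1.70 (adjusted p = 0.252), Hk2, a hexokinase gene, 1.11 (adjusted p = 0.32), and Pgk1 1.24 (adjusted p = 0.379). This list also moved with FLAG-SMN IP replicate 1, which lay 0.93 above the mean of replicates 2 and 3; without it the median was 0.27.

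**Figure D3:**
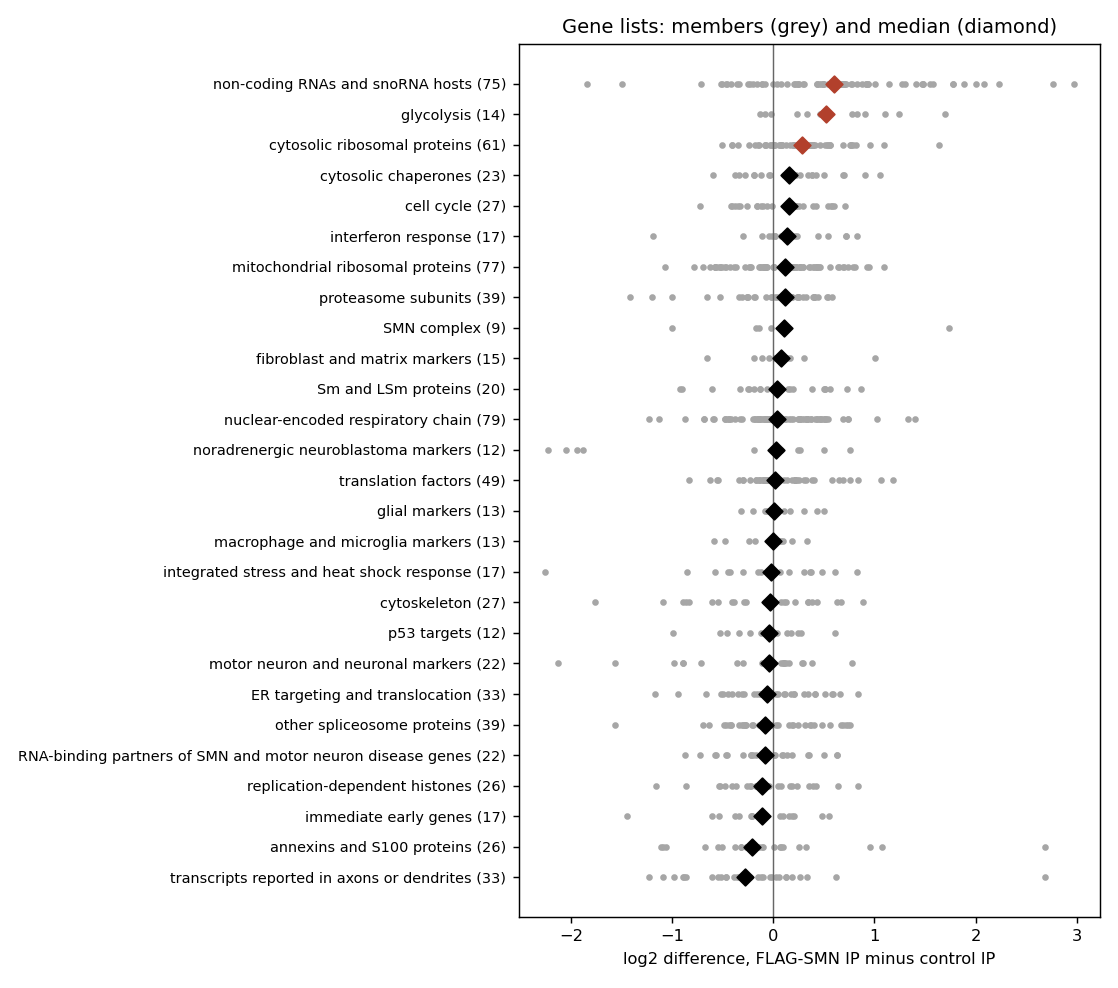
Log2 difference between FLAG-SMN IP and control IP (x axis) for the members (grey points, 1 brightest probe set per gene) and the median (diamond) of 27 gene lists (y axis, number of genes in brackets), with red diamonds where camera with its preset correlation gave an adjusted p under 0.05. The red lists have medians of 0.60, 0.52 and 0.28; none of them passed with an estimated correlation.

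The remaining 24 tested lists did not pass. SMN complex genes had a median of 0.11 over 9 genes (adjusted p = 0.525); apart from Smn1, Gemin7 had the smallest p (mean log2 value 6.84 against 7.85, adjusted p = 0.413), and Smn1 was the 1 gene higher when adjusted over the list alone, with 0 over all probe sets. The genes of Sm and LSm proteins (median 0.039, adjusted p = 0.549) held Lsm12 at -0.92 and Lsm3 at 0.50, and other spliceosome protein genes (median -0.079, adjusted p = 0.855) held Sf3a2 at -1.57 and Snrpa1 at 0.76. RNA-binding partners of SMN and motor neuron disease genes had a median of -0.084 (adjusted p = 0.525), with 0 higher and 4 lower at an unadjusted p under 0.05, among them Wdr77 (-0.57) and Atxn2 (-0.57).

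Transcripts reported in axons or dendrites had a median of -0.28 over 33 genes, with 2 higher and 7 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0748). The list holds both Anxa2 (2.69) and Map2 (-1.09), and Anxa2 was the 1 member passing when adjusted over the list alone, with 0 over all probe sets. Without FLAG-SMN IP replicate 1 its median was -0.35 and it passed (adjusted p = 0.000513); it also passed without control IP replicate 1, at -0.23 (adjusted p = 0.0441). It did not pass without FLAG-SMN IP replicate 2 (-0.14) or 3 (-0.21) or without control IP replicate 2 (-0.17), nor, over all 5 arrays, with an estimated correlation (adjusted p = 0.851). Motor neuron and neuronal markers had a median of -0.044 (adjusted p = 0.369), with Snap25 (-2.13) and Syp (-1.56) as the 2 lower members when adjusted over the list alone and 0 over all probe sets. FLAG-SMN IP replicate 1 lay 0.64 above replicates 2 and 3 on these markers, and without it the list passed at -0.17 (adjusted p = 0.000513). The median was positive without FLAG-SMN IP replicate 2 (0.013) or 3 (0.14) or control IP replicate 1 (0.068), and over all 5 arrays the list had adjusted p = 0.851 with an estimated correlation.

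Genes of the noradrenergic neuroblastoma list went both ways. The list's median was 0.021, its mean -0.54 and its test pointed down (12 genes, adjusted p = 0.369); adjusted over the list alone, 1 was higher and 4 lower, with 0 over all probe sets. The lower members were the enzyme genes Th (-1.94) and Dbh (-2.23) and the granin genes Chga (-1.88) and Chgb (-2.06), and the higher member was Ddc (0.76), another enzyme of catecholamine synthesis. Annexin and S100 genes (median -0.22, adjusted p = 0.311) likewise divided, with Anxa2 and Anxa3 (1.07) higher and S100a16 (-1.11), S100a1 (-1.09) and S100a3 (-1.06) lower when adjusted over the list alone, and 0 over all probe sets. Cytoskeletal genes (median -0.038, adjusted p = 0.547) had Tmsb10 (0.89) higher and Tubb4a (-0.89) and Map2 lower on the same criterion, with 0 over all probe sets.

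Cell cycle genes had a median of 0.15 (27 genes, adjusted p = 0.525), but the control IP arrays differed on this list by -1.10 (replicate 1 minus replicate 2). Birc5 gave 0.71 and Pcna -0.41. The median was -0.60 without control IP replicate 1 (adjusted p = 0.00154), 0.60 without control IP replicate 2 (adjusted p = 1.47e-07), 0.37 without FLAG-SMN IP replicate 1 (adjusted p = 0.00127) and -0.075 without FLAG-SMN IP replicate 3. FLAG-SMN IP replicate 1 differed from replicates 2 and 3 by -0.72 on this list. These p-values use the preset correlation; over all 5 arrays the list had adjusted p = 0.951 with an estimated correlation. Replication-dependent histone genes had a median of -0.11 and a mean of -0.092 while the test pointed up (adjusted p = 0.855). On the histone list FLAG-SMN IP replicate 1 differed from replicates 2 and 3 by -1.19, and without it the median was 0.45 (adjusted p = 1.89e-05 with the preset correlation). Over all 5 arrays the histone list had adjusted p = 0.951 with an estimated correlation, and its median was 0.099 without control IP replicate 2.

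Markers of other cell types gave no shift that passed. Glial markers had a median of 0.0049 (13 genes, adjusted p = 0.525) and macrophage and microglia markers 0.00049 with a test pointing down (13 genes, adjusted p = 0.82), with 0 members of either list at an unadjusted p under 0.05. Fibroblast and matrix markers had a median of 0.079 (adjusted p = 0.525), with Sparc at 1.01 and Pdgfrb at -0.66. Stress-related lists also did not pass. The integrated stress and heat shock list had a median of -0.022 (adjusted p = 0.82), within which the cystine transporter gene Slc7a11 (-2.26) was the 1 member lower when adjusted over the list alone and 0 passed over all probe sets. For p53 targets the median was -0.039 (adjusted p = 0.549), for immediate early genes -0.12 (adjusted p = 0.525) and for interferon response genes 0.13 (adjusted p = 0.311). In each of these lists 1 member was lower when adjusted over the list alone, Trp53inp1 (-0.99), Fosl1 (-1.45) and Cxcl10 (-1.19), with 0 over all probe sets.

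Of the lists for mitochondria and protein turnover, nuclear-encoded respiratory chain genes had a median of 0.036 (79 genes, adjusted p = 0.262), with Cox7a1 (1.33) and Cox4i2 (1.40) higher when adjusted over the list alone and 0 over all probe sets. Mitochondrial ribosomal proteins had a median of 0.12 (adjusted p = 0.262; Mrpl30 0.92), and translation factors 0.021 (adjusted p = 0.311; Eif3m 1.18). Cytosolic chaperones had a median of 0.15 (adjusted p = 0.193; Cct4 0.90). These 4 lists changed with single arrays, each p below using the preset correlation, and over all 5 arrays each had adjusted p = 0.851 with an estimated correlation. Mitochondrial ribosomal proteins passed without FLAG-SMN IP replicate 1 (0.14, adjusted p = 0.01), but the median was 0.033, 0.040 and 0.041 without FLAG-SMN IP replicate 2, FLAG-SMN IP replicate 3 and control IP replicate 2, and did not pass. The respiratory chain passed without FLAG-SMN IP replicate 1 (0.17, adjusted p = 0.00112), and its median was 0.015, 0.0067, 0.16 and -0.010 without FLAG-SMN IP replicate 2, FLAG-SMN IP replicate 3, control IP replicate 1 and control IP replicate 2. Translation factors passed without FLAG-SMN IP replicate 2 (0.13, adjusted p = 0.049) or control IP replicate 2 (0.12, adjusted p = 0.0403), and their median was 0.044 without FLAG-SMN IP replicate 1 and -0.00061 without replicate 3. Chaperones passed without the same arrays (0.23, adjusted p = 0.023, and 0.20, adjusted p = 0.0339), and their median was 0.068 without FLAG-SMN IP replicate 1 and 0.10 without control IP replicate 1. Proteasome subunits had a median of 0.11, a mean of -0.0086 and a test pointing up (adjusted p = 0.525). Genes for targeting and translocation at the endoplasmic reticulum had a median of -0.063 (adjusted p = 0.896; Dad1 -1.17). Only 2 mitochondrially encoded transcripts were measured, COX2 (0.30) and ND3 (-0.031), too few for a list test.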

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

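The test of all probe sets in the table was chosen after the data were seen; the other alternatives were planned. The number of calls was the least stable result. Against 4 higher and 5 lower, cyclic loess gave 0 and 0 in limma, centring on the brighter probe sets 16 and 25, array weights 26 and 60, and the mean of all probe sets of a gene 10 and 44; trend and robust moderation gave 8 lower. Testing every probe set in the table gave 0 and 0. Leaving out 1 array gave 0 to 159 higher and 0 to 191 lower; all the calls above 0 came from leaving out FLAG-SMN IP replicate 1, which had the lowest array weight (0.453). With control IP replicate 1 or 2 left out, the lone control array is assumed to vary like the other group. The 9 called probe sets were among the calls under centring, array weights and moderation. The 2-fold count of 325 and 460 became 902 and 1409 at 1.5-fold, 732 lower with every probe set in the table, and 353 to 475 higher and 351 to 728 lower with 1 array left out, 728 being the value without control IP replicate 1. Scaling moved the median of all probe sets by less than 0.1, to 0.0112 or 0.0521 from 0.018. The 3 higher lists were called under both scalings, brighter probe sets only, moderation, array weights, the mean of all probe sets of a gene, the block and with any of the 5 arrays left out, but 0 were called with an estimated correlation or fry. Array weights gave 6 higher and 2 lower lists, and leaving out 1 array 3 to 7 and 0 to 2. The 7 higher lists came without FLAG-SMN IP replicate 1, and 2 lower lists came without that array or without control IP replicate 1. Where calls were lost or gained, the cause was not tested. The planned exclusion of cross-hybridising probe sets by ID ending was not run, since these IDs are plain numbers. No file marks a background level; the presumed control probe sets had medians of 4.30 to 4.54, and folds against values below them are not given.

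With the replicate number as a block, 0 probe sets were called higher and 0 lower in limma, with 443 and 619 in the 2-fold count and 3 lists higher. Numbers 1 and 2 are the only shared ones, and with 2 control arrays, whose deviations mirror each other, whether the numbers pair the samples could not be told. The blocked medians of opposite sign were SMN complex -0.029, translation factors -0.00061, cell cycle -0.075, neuronal markers 0.14 and p53 targets 0.034; Gap43 was 0.22.

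Of 27 list medians, 17 changed sign somewhere, as did 3 of 75 named probe sets, and the cause was not tested. Cyclic loess gave translation factors -0.013, glial markers -0.023, macrophage markers -0.023 and the stress list 0.011; centring gave the stress list 0.012 and ND3 0.0035. Brighter probe sets only gave noradrenergic markers -0.10. Array weights gave histones 0.28, noradrenergic markers -0.022, glial markers -0.011, macrophage markers -0.025, the stress list 0.029 and Nrn1 -0.040. With 1 array left out, the ranges that crossed 0 were SMN complex -0.13 to 0.30, Sm and LSm -0.0092 to 0.038, other spliceosome -0.17 to 0.029, respiratory chain -0.010 to 0.17, translation factors -0.00061 to 0.13, histones -0.40 to 0.45, endoplasmic reticulum -0.14 to 0.094, cell cycle -0.60 to 0.60, SMN partners -0.19 to 0.023, neuronal markers -0.17 to 0.14, noradrenergic -0.13 to 0.043, glial -0.16 to 0.19, macrophage -0.18 to 0.22, fibroblast -0.039 to 0.17, stress -0.13 to 0.11, p53 targets -0.20 to 0.034 and immediate early -0.29 to 0.15. Among genes they were ND3 -0.064 to 0.0025, Nrn1 -0.22 to 0.54 and Gap43 -1.39 to 0.27.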

Other observations

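The tests of snoRNAs against host genes and brightness, of box classes, of hypoxia and catecholamine genes and of FLAG-SMN IP replicate 1 were chosen after the results they bear on were at least partly seen. The box C/D pairing was added after the pooled pairing was undecided, the pairing without low-signal members after both, and the conditions on box classes, cell state and small RNA yield were set after their values were seen. Sterol synthesis genes were lower in FLAG-SMN IP as a group. The list was drawn up after Cyp51 (log2 difference -1.61) and Nsdhl (-2.01) were noticed, and left both out. All 17 other genes had negative differences, 11 of them at an unadjusted p under 0.05, with a median of -0.70. Camera gave p = 4.53e-10, and p = 0.0209 with an estimated correlation. Both are unadjusted, unlike the p-values of the fixed lists. They come from the same arrays that prompted the list, so they are no independent test. Sqle, a rate-limiting enzyme of the pathway, gave -1.65 (adjusted p = 0.0939), Idi1 -1.32 and Dhcr7 -0.94. Without FLAG-SMN IP replicate 1 the median was -0.71. Whether these transcripts were less abundant in the tagged cells or less retained by the beads was not analysed here, as no RNA from before precipitation was used.

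Hypoxia-inducible genes lay on the higher side. A list of 18, drawn up without the already noticed Bnip3 (1.87) and Pfkp, had a median of 0.52. In it 5 were higher and 0 lower at an unadjusted p under 0.05. Camera gave p = 6.84e-05, and p = 0.252 with an estimated correlation, both unadjusted and from the arrays that prompted the list. Higd1a gave 1.26 and Pdk1 0.76. FLAG-SMN IP replicate 1 lay 0.80 above replicates 2 and 3 on this list, and without it the median was 0.33.

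Annotated snoRNAs (53 genes) had a median log2 difference of 0.62, above 100% of 10000 random gene sets matched on mean signal, which argues against brightness as the cause. Box C/D snoRNAs were taken by symbol (starting with Snord), and the genes around them by position without regard to strand. The snoRNAs within Rian carry other symbols and entered only the full set of pairs. Of the box C/D snoRNAs, 15 could be paired with the measured gene around them. They exceeded it by a median of 0.935 (95% bootstrap interval over 13 host genes 0.226 to 1.27). Without 3 pairs that have a member at or below the presumed controls the excess was 0.805 (-0.0622 to 1.18), and over all 31 snoRNA pairs it was 0.371 (-0.143 to 0.74), so signal of the mature host transcript stays open. The mean over 31 box C/D snoRNAs was 0.90 against 0.25 over 20 box H/ACA snoRNAs (permutation p = 0.00447 over genes, which are not independent replicates), but without FLAG-SMN IP replicate 1 the means were 1.13 and 0.89 (p = 0.163), so the class difference rests on that array. A higher snoRNA level in the tagged cells also stays open, because RNA of the lysates was not analysed here.

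FLAG-SMN IP replicate 1 differed from replicates 2 and 3 in several classes of RNA at once. Terc, the telomerase RNA, was 103-fold lower there (6.03 against 12.8 and 12.7, with 12 and 11.9 in the controls), and Scarna13 was 8.66-fold lower, whereas n-R5s136 was 2.69-fold and Gap43 9.70-fold higher. Its Smn1 value exceeded the highest control array by 1.78, whichever RNA that probe set reads, and this 1 gene argues against a control precipitate under the wrong label. A lower yield of all small RNAs could not be settled, since box C/D and box H/ACA snoRNAs differed in their fall by 1.23 (bootstrap interval 0.461 to 1.93, against a bound of 0.5; medians -0.17 and -2.03). Another cell state at harvest may also contribute, but the values do not single it out. The neuronal list median of replicate 1 lay above 100% of matched random sets and its cell cycle median above 0%. Glycolysis genes likewise lay above 100%, and histones and snoRNAs above 0%. Random sets hold unrelated genes, whereas the estimated correlation was 0.825 for cell cycle and 0.409 for neuronal genes, so these percentiles cannot decide. The control arrays differed from each other by -1.10 on cell cycle genes (-0.72 for replicate 1 minus replicates 2 and 3) and by 0.15 on neuronal genes (0.64).

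Some genes of catecholamine synthesis, secretory granules and nicotinic receptors, picked after their values were seen, had negative differences: Chrna3 (-3.95), Dbh (-2.23), Th (-1.94), Scg2 (-1.53) and Chrnb4 (-1.26). The synthesis enzyme gene Ddc went the other way (0.76). A candidate explanation is a lower level of these transcripts in the tagged cell line, but the members of the noradrenergic list went both ways (adjusted p = 0.369), which decides nothing. Enrichment by the beads cannot be told apart from the cells' RNA level for these genes, because lysate RNA was not analysed here. Without FLAG-SMN IP replicate 1 the limma adjusted p was 0.00515 for Chrna3, 0.0085 for Th, 0.0333 for Scg2 and 0.0386 for Dbh. Chrnb4 (0.0757) and Ddc (0.117) did not pass there. Leaving out FLAG-SMN IP replicate 2 or 3 instead left 0 probe sets past the threshold.

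Other splits of the 5 arrays into 3 and 2 gave at most 2 probe sets past the threshold, against 9 for the real groups, which 1 of the 10 splits reached; the splits are too few for a share under 0.05. The 6573 probe sets left out as presumed controls held 0 past the adjusted threshold in limma and 476 at an unadjusted p under 0.05, with a smallest adjusted p of 0.588. Those 476 exceed the share of 0.05 that chance gives, so an excess over chance was not confined to the tested probe sets.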
